A study of Musca domestica with 6 samples.

How the data were processed

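RNA was measured by sequencing in 6 libraries made from whole larvae of the housefly, Musca domestica, in the second larval instar (instar 2). Larvae had been injected with double-stranded RNA against MdCht9, a chitinase gene, or against GFP, the gene of a jellyfish fluorescent protein that serves as a control sequence, and were collected 24 h later. Double-stranded RNA triggers RNA interference, the degradation of transcripts that match it. Per the labels' protocols, RNA was extracted with Trizol and 3 µg went into each library. Samples were grouped by their titles into dsMdCht9 (3 samples) and dsGFP (3 samples). One phrase of the series description names a retinal sample, which differs from the sample labels, and the sample labels were followed. The labels do not say that the 3 samples of a group came from separate pools of larvae, so the p-values measure the spread between these samples, which may be partly technical.

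The deposited table held raw read counts per gene for each of the 6 samples, per the file headers. HISAT2 2.1.0, StringTie 1.3.2d and HTSeq 0.6.0 are named in the submitters' processing notes, with no roles given. The genome build, the use of strand, the enrichment for polyadenylated RNA and the treatment of reads that map to several places are not given in the sources used here. Gene families with near-identical members, such as trypsins, cuticle proteins and arylphorins, are therefore uncertain gene by gene. Positions are those of the deposited table, on scaffolds of an assembly it does not name. The authors' deposited table also gave a mean normalized signal per gene, a fold change as a ratio, a log2 fold change, and a p-value with its adjusted p-value for dsMdCht9 against dsGFP. Recomputing the authors' mean signal as the mean of the deposited counts divided by median-of-ratios size factors gave a largest difference of 5.2e-10. The mark of significance in the authors' deposited table differed in 0 genes from the rule of a p-value under 0.05 with a change of more than 1.5-fold.

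The table held 14227 genes, of which 13278 were protein-coding and 865 were long non-coding RNAs, and 0 rows named no gene. Total counts were 14107417, 13560866 and 12876941 in dsMdCht9 replicates 1, 2 and 3, and 15439421, 15314878 and 15414131 in dsGFP replicates 1, 2 and 3. Pairs of samples within a group differed far beyond sampling noise, with chi-square values of 33.6 to 143.5 per degree of freedom over the tested genes. The files are thus not copies of one library, which does not show that they came from separate pools.

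Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr, which left 10644, and scaled with the trimmed mean of M-values (TMM). The main test was the two-sided quasi-likelihood F-test of edgeR 4.0.16 with robust estimation, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Values per sample are CPM, the read counts scaled to a common library size after TMM scaling. The biological coefficient of variation was 0.306. Gene lists were tested with camera from limma 3.58.1, which compares the genes of a list with all other genes, at its preset inter-gene correlation of 0.01, with adjustment over 26 lists. The tests, the 26 lists, the rule for named genes and most alternatives were fixed before the data were examined. Camera with an estimated correlation and fry, which tests a list on its own, were alternatives. For each list, the mean log2 CPM per library was also compared with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 samples against 3.

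On simulated counts with the means and spread of these 10644 genes, in which 200 genes were changed, edgeR called 77 of 100 genes changed 4-fold, 14 of 100 genes changed 2-fold, and 2 unchanged genes. DESeq2 1.42.0 called 88, 34 and 35, and limma-voom called 69, 9 and 2. A simulated list of 60 genes shifted by 0.5 on the log2 scale gave a camera p of 5.64e-17, and an unshifted list gave 0.74. These lists were drawn with no correlation between genes, so they do not test the preset correlation.

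Each list holds the genes whose description matches fixed terms: chitinases and chitinase-like proteins, chitin synthesis and modification, cuticle proteins, peritrophic matrix and chitin-binding proteins, ecdysteroid and moulting factors, juvenile hormone factors, antimicrobial peptides, immune recognition and signalling, lysozymes, melanin and cuticle tanning enzymes, trypsins and chymotrypsins, other digestive enzymes, cytochrome P450, other detoxification enzymes, heat shock proteins, RNA interference machinery, cytosolic ribosomal proteins, oxidative phosphorylation, storage and lipid transport proteins, muscle proteins, haemocyte markers, neuronal markers, DNA replication and mitosis, chemosensory proteins, fatty acid and cuticle wax synthesis, and protease inhibitors. The rule for named genes took the targeted gene if an annotation named it, all tested genes of the chitinase list, up to 4 members of smallest p from each list, and the 10 higher and 10 lower genes of largest change that passed the threshold with a mean log2 CPM of at least 1, no overlap between the groups and an informative description. If none passed, the rule took the 5 of smallest p, as not passing. That fallback was read as 5 in each direction that met the other criteria, and up to 2 members were named from lists that did not pass camera, both readings being settled after values had been seen. Genes outside the rule are said to have been chosen after their values were seen.

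MdCht9 was looked for by name, and 0 genes of the deposited table and 0 of 21256 genes of the RefSeq annotation of assembly GCF_030504385.1 read Cht9 or chitinase 9. All 30 genes of the chitinase list are therefore given, of which the filter left 27 for testing, and none is called the target.

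The replicate numbers of the titles were checked for pairing by the correlation, across genes, of each sample's deviation from its group mean. Samples of the same number correlated at 0.24, 0.39 and 0.65 for numbers 1, 2 and 3. Each was above 0.1, the rule by which the numbers were taken to pair the samples. Of the pairs of different number, dsMdCht9 replicate 2 with dsGFP replicate 1 correlated at 0.32, above number 1, and the others lay between -0.51 and 0.08, so only number 3 stood clearly apart. The deviations of a group sum to 0, so an outlying number 3 in both groups makes numbers 1 and 2 correlate whether or not they pair. The rule thus gives no evidence of pairing for numbers 1 and 2. These correlations were seen together with the number of genes called in edgeR with the replicate block, which was 0 as without it. The pairing is a reading of the data, since the labels give the numbers no meaning, and a fit with the replicate block is given where it changes a call. The alternatives were size factors of DESeq2 within edgeR, library size alone, no filter, a filter of 5 CPM in 3 samples, the replicate block, each sample left out in turn, the Wald test of DESeq2, limma-voom, a log2 fold change of at least 1, and an adjusted p under 0.01. Chosen after seeing the data were the fits without both samples numbered 3, DESeq2 with the replicate block, cyclic loess offsets that remove a trend of fold change with abundance, and a chitinase list defined by the glycosyl hydrolase 18 domain. Alternatives planned for normalized values did not apply, since the table held counts.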

Results

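RNA levels were measured in whole housefly larvae 24 h after injection of double-stranded RNA against the chitinase gene MdCht9 or against GFP, with 3 libraries in each group. Chitinases degrade chitin, the polymer of the cuticle and of the peritrophic matrix that lines the insect gut. Libraries held between 12876941 and 15439421 counted reads, and 10644 genes were tested. The 10 most abundant genes took 13.2% to 17.9% of the counts of a library. The first principal component of log2 CPM held 49.3% of the variance and set both samples numbered 3 apart from the others, at 48.2 for dsMdCht9 replicate 3 and 40.2 for dsGFP replicate 3 against -33.5 to -3.04 for the remaining 4 libraries. Values below are mean CPM ± SD over the 3 libraries of a group, and log2 fold changes (dsMdCht9 minus dsGFP) ± SE.

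Most chitinase genes had lower mean levels after injection of RNA against MdCht9, by a median log2 fold change of -0.23, and none passed the test on its own. Lists of genes for digestion, cuticle, ribosomes and mitochondrial respiration lay lower too, by medians between -0.41 and -0.13 (camera at its preset correlation, with 0 lists called at an estimated one). No list lay higher past the threshold, and edgeR called no single gene, with 381 genes at an unadjusted p under 0.05 and 13 called by DESeq2.

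The first question was whether the targeted transcript was lower after injection of its own double-stranded RNA. No annotation used here names MdCht9, so its level is not reported as such, and all 30 genes described as chitinases or chitinase-like proteins are given instead, of which 27 were tested. Of these 27, 23 were lower and 4 were higher in dsMdCht9, and 0 passed the threshold over all genes or adjusted over the list alone. The smallest p belonged to LOC101893192, described as acidic mammalian chitinase-like (scaffold NW_004764717.1, positions 248594 to 250692), at 10.7 ± 4.37 CPM in dsMdCht9 and 22.1 ± 4.69 in dsGFP. Its log2 fold change was -1.05 ± 0.32 (edgeR adjusted p = 0.999), with all 3 dsMdCht9 libraries below all 3 dsGFP libraries. With the replicate block, DESeq2 gave this gene an adjusted p of 0.0313, while DESeq2 without it gave 0.677 and edgeR with it gave 0.396. In the authors' deposited table its log2 fold change was -1.05 with an adjusted p of 0.562. That table marks it as significant, by an unadjusted p of 0.00324 and its fold change. Reads from the injected RNA itself, if any were sequenced, would add to the counts of the targeted gene.

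Among the other genes of the list, LOC101893092 (probable chitinase 3) was at 70.8 ± 12.2 CPM in dsMdCht9 and 100.8 ± 17.8 in dsGFP, with a log2 fold change of -0.51 ± 0.20. Its annotation holds no glycosyl hydrolase 18 domain, the catalytic domain of chitinases. LOC101898296 (endochitinase) differed by -0.52 ± 0.23, and LOC101894621 (acidic mammalian chitinase) lay the other way at 0.33 ± 0.15. Only LOC101893192 and LOC101893092 had an unadjusted p under 0.05 among the 27, and each of the 27 had an edgeR adjusted p of 0.999. Of the further genes described as probable chitinases, the log2 fold changes were -0.65 ± 0.63 for LOC101889312, -0.59 ± 0.40 for LOC101888642, -0.57 ± 0.45 for LOC101895285, -0.37 ± 0.33 for LOC101894465, -0.23 ± 0.19 for LOC101895047 and -0.10 ± 0.22 for LOC101899985. With 1 library left out these ranged from -1.29 to -0.28, -1.09 to -0.31, -0.83 to -0.25, -0.54 to -0.044, -0.33 to -0.012 and -0.21 to 0.066, in the same order. LOC101893352, LOC101897146 and LOC101894219, of other chitinase descriptions, and LOC101888821 and LOC101899936, called chitinase-like, lay between -0.14 and 0.11. With 1 library left out they lay between -0.38 and 0.21. Imaginal disc growth factors are relatives of chitinases that lack the catalytic residue. Among the genes so described or called chitinase-like, LOC101900748 (Idgf3) differed by -0.86 ± 0.42, LOC101900298 by -0.36 ± 0.22 and LOC101897958 (Idgf1) by -0.32 ± 0.20. With 1 library left out they ranged from -1.10 to -0.49, -0.52 to -0.15 and -0.50 to -0.20. LOC101890724 (Idgf4) was the most abundant gene of the list, at 1165 CPM in dsMdCht9 and 1368 in dsGFP, with a log2 fold change of -0.23 ± 0.19 (-0.36 to -0.13 with 1 library left out). LOC101892322, LOC101898126, LOC101898304, LOC101898595, LOC101900924, LOC101891535, LOC101889717 and LOC109611916 lay between -0.24 and 0.35, or between -0.62 and 0.59 with 1 library left out. The filter on low counts removed 3 genes of the list. LOC105261552 (Idgf1) had 0, 1 and 0 reads in dsMdCht9 replicates 1, 2 and 3 and 2, 4 and 9 in dsGFP replicates 1, 2 and 3, with a log2 fold change of -3.70 in the authors' deposited table, which marks it as significant with no adjusted p, and -3.40 ± 1.19 in edgeR without a filter (adjusted p = 1.00). LOC109613348 (endochitinase 2-like) had 1 read in dsMdCht9 and 5 in dsGFP (authors' log2 fold change -2.19), and LOC101898016 had 2 and 1 (0.81). Counting by library size alone moved the median of all genes by 0.12 on the log2 scale, and 6 of the genes near 0 then changed sign.

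**Figure D1:**
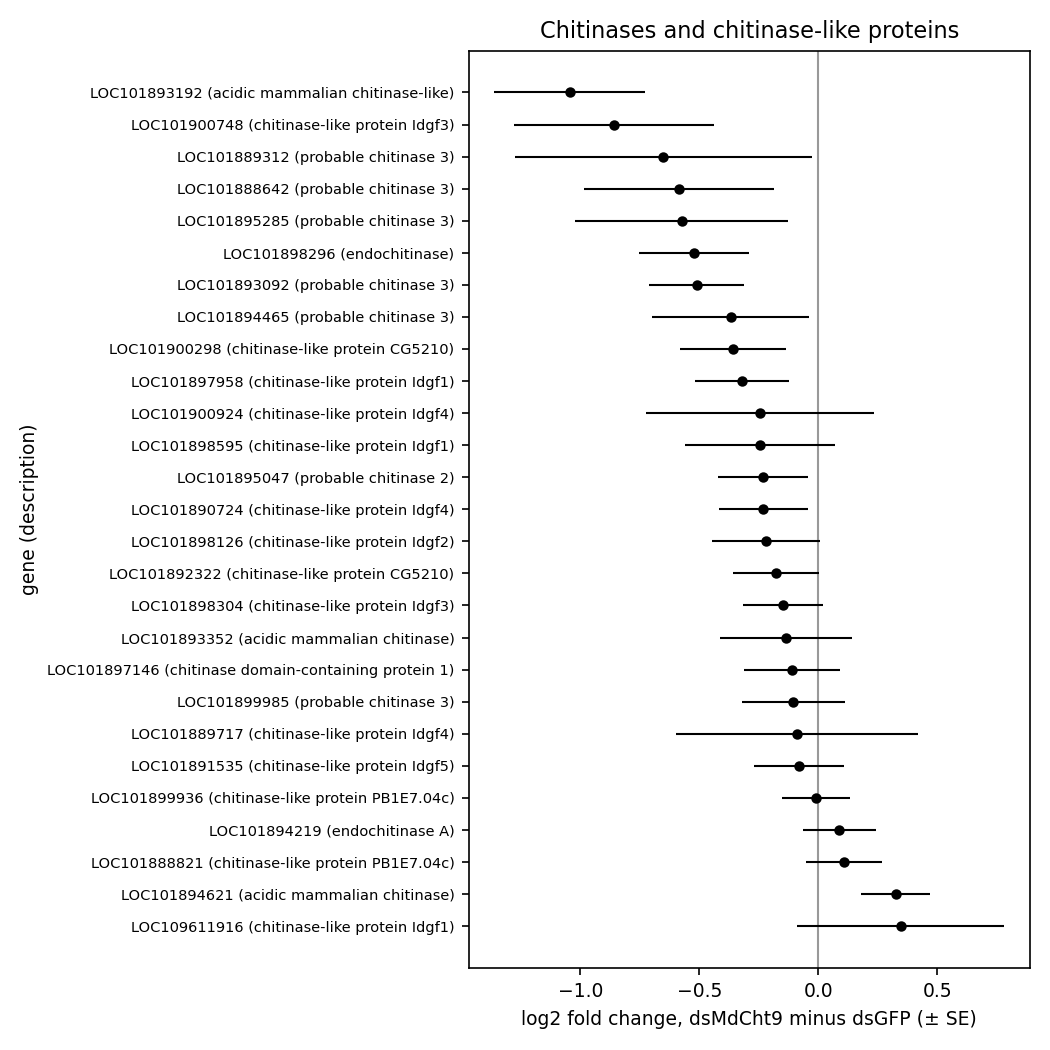
Log2 fold change of each of the 27 tested chitinase and chitinase-like genes (dsMdCht9 minus dsGFP, horizontal axis) with its SE as a bar, sorted from lowest to highest, with the gene and its description on the vertical axis. Most points lie left of 0, LOC101893192 farthest at -1.05, and 6 of the genes near 0 changed sign when counts were scaled by library size alone.

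As a list, the chitinases lay lower than other genes, with a median log2 fold change of -0.23 (camera adjusted p = 0.00189, and adjusted p = 0.526 with an estimated correlation). The mean level of the list was lower in every dsMdCht9 library than in every dsGFP library, at -0.19, -0.28 and -0.27 in dsMdCht9 replicates 1, 2 and 3 against -0.17, 0.11 and 0.05 in dsGFP replicates 1, 2 and 3 on the log2 scale relative to the dsGFP mean (exact permutation p = 0.1, the smallest 3 against 3 samples can give). The call was lost without dsGFP replicate 3 (median -0.15, adjusted p = 0.0549) and without both samples numbered 3 (median -0.17, adjusted p = 0.0614), and without dsGFP replicate 1 the median was -0.36.

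The second question was which genes differed between the groups. In edgeR's test 0 genes passed an adjusted p of 0.05, with a smallest adjusted p of 0.675. At an unadjusted p under 0.05 there were 381 genes, 210 higher and 171 lower, where 532.2 would be expected by chance. The groups did not overlap in 874 genes, 8.21% of those tested. Chance gives 10% if no samples resemble each other across the groups. Some samples did so by replicate number, so neither the 8.21% nor the 381 genes can be read as fewer than chance gives. With the replicate block edgeR again called 0 genes, with a smallest adjusted p of 0.0743. At an unadjusted p under 0.05 there were then 888 genes, above the 532.2 expected, and more were lower (519) than higher (369). DESeq2 called 13 genes, 8 higher and 5 lower, and with the replicate block it called 91, 16 higher and 75 lower, which included the same 13. Limma-voom called 0, with 379 genes at an unadjusted p under 0.05. The authors' deposited table held the same 13 genes at an adjusted p under 0.05, and marked 378 genes as significant, 162 higher and 216 lower, by unadjusted p and fold change. For the genes named here, the log2 fold changes of that table equal those of DESeq2 on the same counts. The shared 13 genes are therefore no separate support.

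None of the genes named next passed edgeR's threshold, and the naming rule behind the first 10 admitted only genes with no overlap between the groups. The 5 higher genes of smallest p with an informative description were LOC105262473 (putative ATP-dependent RNA helicase me31b, related to a protein that represses stored messenger RNA), LOC105262387 (Mth-like G-protein coupled receptor), LOC101896429 (retinaldehyde-binding protein 1-like), LOC101900671 (transmembrane protein 18) and LOC101895807 (spitz-like, related to a ligand of the epidermal growth factor receptor). LOC105262473 was at 25.7 ± 8.47 CPM in dsMdCht9 and 7.94 ± 0.464 in dsGFP, a log2 fold change of 1.69 ± 0.27 (edgeR adjusted p = 0.675). LOC101897835, a gene of the same description with which reads could be shared and which was chosen after its values were seen, was at 123.6 and 113.0 CPM. LOC105262387 was at 4.64 ± 1.95 and 0.654 ± 0.213 CPM, a log2 fold change of 2.81 ± 0.46. The log2 fold changes of LOC101896429, LOC101900671 and LOC101895807 were 1.43 ± 0.24, 1.69 ± 0.33 and 1.48 ± 0.30. DESeq2 called the first 4 of these genes and not LOC101895807 (adjusted p = 0.0910, and 0.0493 with the replicate block).

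The 5 lower genes of smallest p with an informative description were LOC101895007 (trypsin eta-like, a digestive protease), LOC101901027 (fructose-1,6-bisphosphatase 1, an enzyme of gluconeogenesis), LOC101893833 (serpin B3, a protease inhibitor), LOC101899206 (cytochrome P450 4d8-like) and LOC101896547 (pancreatic secretory trypsin inhibitor). LOC101895007 was at 2.00 ± 0.509 CPM in dsMdCht9 and 8.36 ± 2.96 in dsGFP, a log2 fold change of -2.06 ± 0.34 (edgeR adjusted p = 0.675). LOC101901027 was the most abundant of them, at 70.5 ± 3.68 and 135.5 ± 17.7 CPM, a log2 fold change of -0.94 ± 0.16. LOC101893833 differed by -0.66 ± 0.14, LOC101899206 by -2.08 ± 0.44 and LOC101896547 by -2.26 ± 0.48. DESeq2 called LOC101895007, LOC101901027, LOC101899206 and LOC101896547, and did not call LOC101893833 (adjusted p = 0.114, and 0.0476 with the replicate block). The other DESeq2 calls, chosen here after their values were seen, were 5 genes without an informative description, of which LOC109613889, LOC109613915, LOC105262480 (all 3 annotated as long non-coding RNAs) and LOC105261563 were higher and LOC101892465 was lower.

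**Figure D2:**
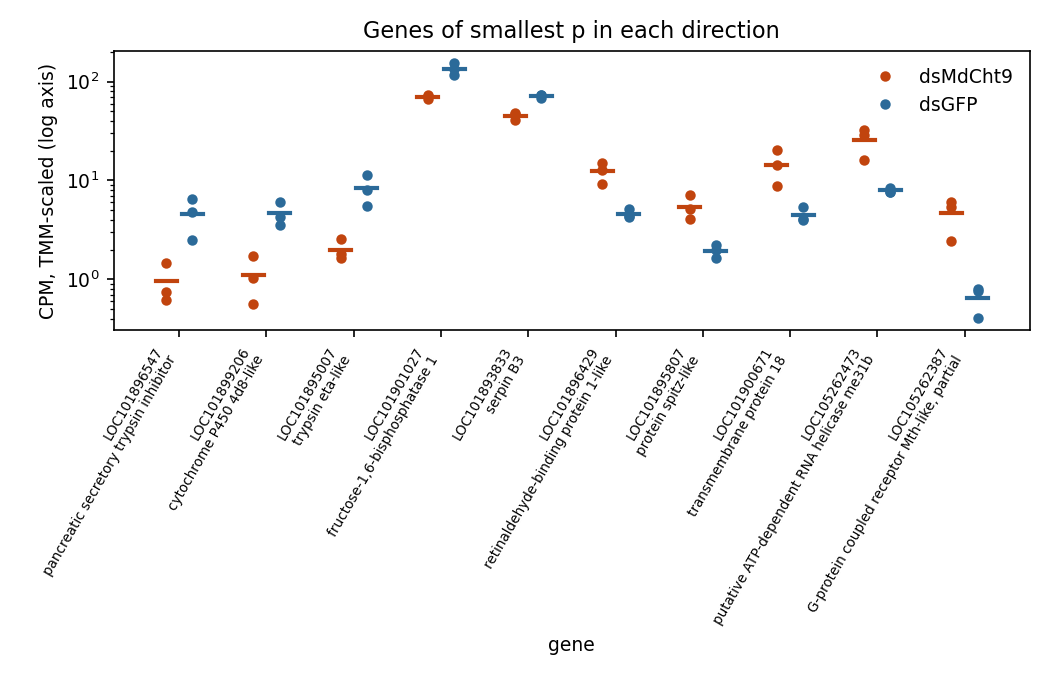
CPM per library on a log axis for the 5 lower and 5 higher genes of smallest p, with dsMdCht9 in orange, dsGFP in blue, each point a library and each bar the mean of 3. Only genes with no overlap between the groups were admitted. They run from LOC101896547 (log2 fold change -2.26) to LOC105262387 (2.81), and none passed the threshold in edgeR.

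The third question was whether groups of functionally related genes moved together. Camera called 11 of the 26 lists, all lower in dsMdCht9, and with an estimated correlation 0 were called. Over all genes 0 members of any list passed, and adjusted over the list alone 1 trypsin and 2 protease inhibitors did. The exact permutation p of the list level per library was 0.1 for chitinases, trypsins and protease inhibitors, 0.2 for other digestive enzymes, 0.3 for ribosomal, oxidative phosphorylation and storage proteins, 0.5 for cuticle proteins and antimicrobial peptides, and 0.6 for peritrophic proteins and cytochrome P450. Within replicate numbers 1, 2 and 3, dsMdCht9 minus dsGFP was -0.021, -0.39 and -0.32 for chitinases, -0.70, -0.22 and -0.53 for cuticle proteins and -0.41, -0.078 and -0.52 for trypsins. It was -0.14, -0.40 and -0.42 for protease inhibitors, -0.21, -0.17 and -0.25 for ribosomal proteins and -0.54, -0.22 and -0.20 for oxidative phosphorylation. The other 5 called lists were not lower in every number. Numbers 1 and 2 gave no evidence of pairing, so being lower in every number is no separate support for a list. With 3 pairs no exact paired p can lie below 0.25. All 11 medians stayed below 0 under each scaling. By library size alone each was nearer 0, at -0.0044 for other digestive enzymes, -0.058 for peritrophic proteins, -0.069 for protease inhibitors, -0.074 for cytochrome P450, -0.080 for ribosomal proteins and -0.10 for chitinases. The others were then at -0.12 for storage proteins, -0.15 for trypsins, -0.20 for oxidative phosphorylation, -0.30 for cuticle proteins and -0.41 for antimicrobial peptides.

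Of 76 trypsins and chymotrypsins, 55 were lower and 21 higher, with a median of -0.27 (camera adjusted p = 4.4e-06, and adjusted p = 0.471 with an estimated correlation), which was -0.17 without dsGFP replicate 1. Besides LOC101895007, which passed when adjusted over the list alone (adjusted p = 0.0367), the members of smallest p were LOC101893185 at -0.58 ± 0.20, LOC101894187 at -1.25 ± 0.43 (DESeq2 adjusted p = 0.00138 with the replicate block and 0.704 without it, edgeR 0.338 with it, and a log2 fold change of -0.63 without dsGFP replicate 1) and LOC101901619 at -1.36 ± 0.49. Of 100 other digestive enzymes, 69 were lower, with a median of -0.13 (adjusted p = 0.00344, and adjusted p = 0.501 with an estimated correlation). Members included LOC101887853, a serine carboxypeptidase, at -0.92 ± 0.26 (DESeq2 adjusted p = 0.0358 with the replicate block and 0.60 without it, edgeR 0.435 with it), LOC101901234, a lipase-related protein, at -0.89 ± 0.26, and LOC101890756, an aminopeptidase, at -2.76 ± 0.85. Protease inhibitors were lower in 19 of 24 genes, with a median of -0.21 (adjusted p = 0.000133, and adjusted p = 0.471 with an estimated correlation), and LOC101893833 and LOC101896547 passed when adjusted over the list alone (adjusted p = 0.0245 for both). The call for other digestive enzymes was lost without dsMdCht9 replicate 1 (median -0.077, adjusted p = 0.149) or dsGFP replicate 3 (-0.078, 0.0616), and without both samples numbered 3 (-0.14, 0.0705). The median was -0.24, -0.21 and -0.19 without dsMdCht9 replicate 2, dsMdCht9 replicate 3 or dsGFP replicate 2. The call for protease inhibitors was lost without dsGFP replicate 3 (median -0.11, adjusted p = 0.135) and without a filter (-0.12, 0.0726), and the median was -0.13 without dsMdCht9 replicate 2 and -0.34 at 5 CPM in 3 samples.

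Cuticle proteins, which bind chitin or form the matrix around it, were lower in 53 of 67 genes, with a median of -0.41 (camera adjusted p = 1.6e-06, and adjusted p = 0.555 with an estimated correlation), which was -0.94 without dsMdCht9 replicate 2 and -0.65 without dsGFP replicate 3. LOC101898819 (larval cuticle protein 5-like) was at 4.19 ± 2.54 CPM in dsMdCht9 and 16.6 ± 7.46 in dsGFP, a log2 fold change of -1.99 ± 0.54 (DESeq2 adjusted p = 5.2e-05 with the replicate block and 0.123 without it, edgeR 0.384 with it), and LOC101893531 and LOC101894551 differed by -0.86 ± 0.35 (-0.42 without dsGFP replicate 1) and -0.84 ± 0.34. LOC101900720 (cuticle protein 16.5-like) lay far the other way at 5.50 ± 1.86, through dsMdCht9 replicate 1, where it was at 88.1 CPM against 1.48 and 3.10 in replicates 2 and 3. The level of this list also moved with the samples numbered 3, at -1.24 in dsMdCht9 replicate 3 and -0.71 in dsGFP replicate 3 on the log2 scale, against -0.27 and 0.06 in the other dsMdCht9 libraries and 0.43 and 0.28 in the other dsGFP libraries. Peritrophic matrix and chitin-binding proteins were lower in 12 of 16 genes, with a median of -0.18 (adjusted p = 0.0331, and adjusted p = 0.634 with an estimated correlation). LOC101889759 (peritrophin-55) was at 208.5 and 341.0 CPM, a log2 fold change of -0.71 ± 0.25, and LOC101888182 (peritrophin-48) differed by -0.50 ± 0.19. This list too was low in both samples numbered 3, at -0.67 and -0.33. Its call was lost without dsMdCht9 replicate 1 (median -0.16, adjusted p = 0.0659), dsMdCht9 replicate 3 (-0.075, 0.846), dsGFP replicate 1 (-0.14, 0.341) or dsGFP replicate 2 (-0.14, 0.130). It was also lost without both samples numbered 3 (-0.19, 0.353), without a filter (-0.17, 0.0726) and with cyclic loess offsets (-0.16, 0.0895), where the median stayed near its -0.18. Without dsMdCht9 replicate 2 or dsGFP replicate 3 the median was -0.44 or -0.34, and at 5 CPM in 3 samples -0.27.

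Ribosomal and mitochondrial genes were lower by small amounts in nearly every member. Of 74 cytosolic ribosomal proteins, 72 were lower, with a median of -0.21 (camera adjusted p = 2.3e-07, and adjusted p = 0.634 with an estimated correlation), which was -0.086 with cyclic loess offsets, -0.12 without dsGFP replicate 1 and -0.14 without dsMdCht9 replicate 3. LOC101892889 (L29) differed by -0.41 ± 0.19 and LOC101895455 (L10) by -0.33 ± 0.16. Of 73 oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, 70 were lower, with a median of -0.32 (adjusted p = 1.3e-13, and adjusted p = 0.555 with an estimated correlation), which was -0.16 without dsGFP replicate 1 and -0.21 without dsMdCht9 replicate 3. LOC101891089 (an NADH dehydrogenase subunit) differed by -1.06 ± 0.31 (DESeq2 adjusted p = 0.0358 with the replicate block and 0.682 without it, edgeR 0.338 with it, and a log2 fold change of -0.66 without dsGFP replicate 1), LOC101893273 by -0.73 ± 0.29 and LOC101898893 by -0.65 ± 0.27. The members of both lists were strongly correlated, at an estimated 0.795 and 0.765, and the oxidative phosphorylation list was low in both samples numbered 3, at -0.55 and -0.35.

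Among immune genes, antimicrobial peptides were lower in 12 of 18 genes, with a median of -0.54 (camera adjusted p = 0.0182, and adjusted p = 0.555 with an estimated correlation). This rested on dsMdCht9 replicate 2, whose list level was -1.42 against -0.12 and 0.01 in replicates 1 and 3, and without it the median was -0.30 and the adjusted p 0.927. The call was also lost without dsGFP replicate 2 (median -0.29, adjusted p = 0.130) or dsGFP replicate 3 (-0.40, 0.0566). The gene of smallest p, LOC101889801 (sarcotoxin-1D-like), lay higher, at 2.16 ± 0.477 CPM in dsMdCht9 and 0.879 ± 0.495 in dsGFP, and the gene attacin(gene5086), described as sarcotoxin II-1-like, differed by -1.41 ± 0.60. Immune recognition genes did not pass (17 of 30 lower, median -0.14, adjusted p = 0.338), with LOC101898661 (peptidoglycan-recognition protein LC-like) at -0.69 ± 0.18, nor did lysozymes (14 of 22 lower, median -0.13, adjusted p = 0.0610), with LOC101895951 at 2580 and 3439 CPM. Lysozymes passed as lower without dsMdCht9 replicate 2 (0.00752), dsGFP replicate 2 (0.0460) or dsGFP replicate 3 (0.0424), with the stricter filter (0.0203), and by library size alone (0.0239), where their median was 0.0039. They did not pass without dsMdCht9 replicate 1 (median -0.093, adjusted p = 0.531), dsMdCht9 replicate 3 (-0.26, 0.331) or dsGFP replicate 1 (-0.16, 0.513). Nor did haemocyte markers pass (6 of 10 lower, median -0.06, adjusted p = 0.651).

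Storage and lipid transport proteins, the amino acid and lipid stores of the larva, were lower in 15 of 17 genes, with a median of -0.23 (camera adjusted p = 0.00571, and adjusted p = 0.555 with an estimated correlation). LOC101893407 (larval serum protein 1 beta chain-like) was at 46.3 and 123.2 CPM, a log2 fold change of -1.41 ± 0.73 with overlapping groups (DESeq2 adjusted p = 0.000122 with the replicate block and 1.00 without it, edgeR 0.396 with it, and a log2 fold change of -0.91 without dsGFP replicate 2), and LOC101888755 (arylphorin) differed by -0.71 ± 0.45, or -0.24 without dsGFP replicate 1 and -1.21 without dsMdCht9 replicate 2. The list was lowest in dsMdCht9 replicate 1, at -1.05, and its call was lost without that library (median -0.062, adjusted p = 0.660) or without dsGFP replicate 1 (-0.22, 0.0641), without a filter (-0.11, 0.127) and with cyclic loess offsets (-0.17, 0.215). The median was -0.44 without dsMdCht9 replicate 2. Cytochrome P450 genes, oxidases of toxins and hormones, were lower in 69 of 111 genes, with a median of -0.19 (adjusted p = 0.0182, and adjusted p = 0.555 with an estimated correlation), including LOC101889524 (CYP12A2-like) at -1.12 ± 0.28 (DESeq2 adjusted p = 0.0192 with the replicate block and 0.345 without it, edgeR 0.396 with it). The list was highest in both samples numbered 3, at 0.11 and 0.21. Its call was lost without dsMdCht9 replicate 1 (median -0.059, adjusted p = 0.783) or dsGFP replicate 3 (-0.057, 0.913). With the replicate block (-0.18, 0.0642), without both samples numbered 3 (-0.17, 0.182) and without a filter (-0.20, 0.104) it was lost too, while the median stayed near its -0.19.

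**Figure D3:**
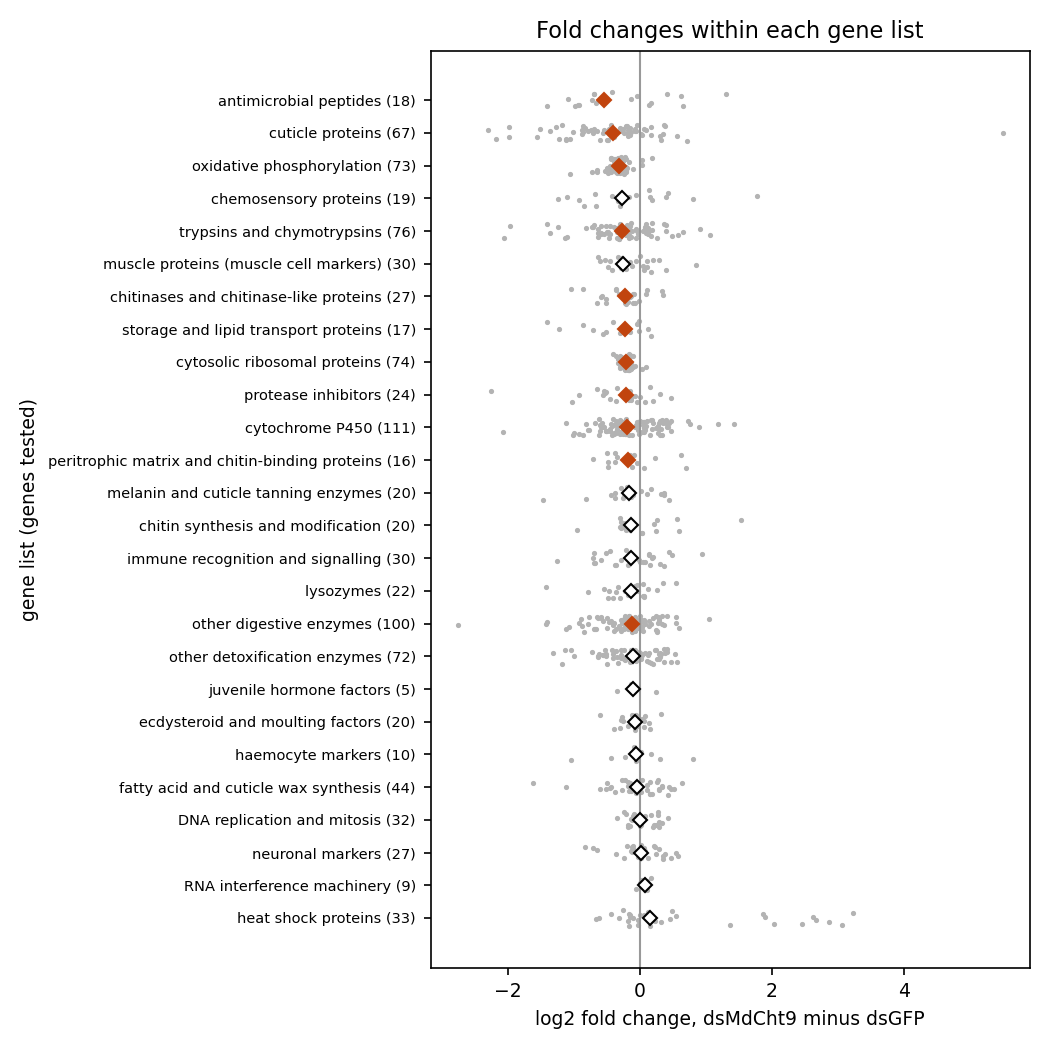
Log2 fold change of every tested gene (grey points) and the median (diamond) of each of the 26 gene lists, dsMdCht9 minus dsGFP, with the number of tested genes in parentheses. Filled diamonds mark the 11 lists called by camera at its preset correlation, which lie between -0.54 and -0.13, and none was called with an estimated correlation.

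The remaining lists did not pass camera. With the replicate block, muscle proteins (20 of 30 lower, median -0.26, adjusted p = 0.0527, and 0.0240 with the block) and chemosensory proteins (12 of 19 lower, median -0.27, adjusted p = 0.0814, and 0.0491 with the block) passed, and with an estimated correlation in the blocked fit neither did (adjusted p = 0.636 for both). Both lists were low in the samples numbered 3, at -0.36 and -0.27 for muscle and at -0.91 and -0.56 for chemosensory proteins. The muscle list was as low in dsMdCht9 replicate 1, at -0.35. Both also passed as lower without dsMdCht9 replicate 2 (4.7e-05 and 0.00700) or dsGFP replicate 3 (0.00531 and 0.0372) and by library size alone (0.0279 and 0.0239), and muscle proteins with the stricter filter (0.0294). Against this, the muscle median was -0.15, -0.15, -0.16 and -0.18 without dsMdCht9 replicate 1, dsMdCht9 replicate 3, dsGFP replicate 1 or dsGFP replicate 2 (adjusted p from 0.266 to 0.599) and -0.085 with cyclic loess offsets (0.362). The chemosensory median was -0.15 without dsMdCht9 replicate 3 (0.653), -0.00088 without dsGFP replicate 1 (0.513), 0.037 without a filter (0.421) and -0.14 with cyclic loess offsets (0.0895). Heat shock proteins had a median of 0.14 and a mean of 0.70 (19 of 33 higher, adjusted p = 0.0790). LOC101891430 (heat shock protein 70) was at 76.9 CPM in dsMdCht9 replicate 3 and between 2.38 and 5.13 in the other 5 libraries, and LOC101897990 (heat shock protein 23-like) at 18.9 against 0.433 to 1.64. The list was called as higher without dsMdCht9 replicate 2 (adjusted p = 0.00116), dsGFP replicate 1 (0.0202) or dsGFP replicate 2 (0.0342), without a filter (0.0346) and with cyclic loess offsets (0.0404). Its median was 0.057, 0.075 and 0.051 without dsMdCht9 replicate 1 (0.125), dsMdCht9 replicate 3 (0.445) or dsGFP replicate 3 (0.913), and 0.0084 without both samples numbered 3 (0.981). Chitin synthesis genes had a median of -0.14 (12 of 20 lower, adjusted p = 0.880), or from -0.13 to -0.015 with 1 library left out. Among them LOC109612747, described as alpha-N-acetylglucosaminidase but annotated as a long non-coding RNA, was at 1.53 ± 0.45. The protein-coding LOC101901729, of the same description and scaffold, was at 0.58 ± 0.24. Tanning enzymes had a median of -0.17 (13 of 20 lower, adjusted p = 0.0814), with LOC101900449 (phenoloxidase 2, which forms melanin) at -1.47 ± 0.53 (-2.25 without dsMdCht9 replicate 1), and passed as lower without dsMdCht9 replicate 3 (0.00892) and by library size alone (0.0417). Their median was 0.032 without dsMdCht9 replicate 1 (0.599). The list of RNA interference machinery had a median of 0.07 (7 of 9 higher, adjusted p = 0.521), with LOC101896691 (Dcr-1) at 0.17 ± 0.16. With 1 library left out, the median ranged from 0.033 to 0.093 and Dcr-1 from 0.097 to 0.28. Ecdysteroid and moulting factors had a median of -0.07 (13 of 20 lower, adjusted p = 0.513), passed as lower without dsMdCht9 replicate 3 (median -0.34, adjusted p = 0.00665), had a median of 0.12 without dsGFP replicate 3 (0.578), and were high in both samples numbered 3, at 0.34 and 0.38. Other detoxification enzymes had a median of -0.11 (43 of 72 lower, adjusted p = 0.129, and 0.0450 without dsMdCht9 replicate 2, with a median of -0.031 and 0.642 without dsMdCht9 replicate 1). The medians were -0.10 for juvenile hormone factors (4 of 5 lower, adjusted p = 0.880), -0.05 for fatty acid and wax synthesis (25 of 44 lower, 0.627) and 0.02 for neuronal markers (15 of 27 higher, 0.651). With 1 library left out, the juvenile hormone median ranged from -0.22 to -0.012 and the neuronal median from 0.035 to 0.22. For DNA replication and mitosis the median was -0.01 while the mean was 0.03 and the test pointed higher (17 of 32 lower, adjusted p = 0.768).

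**Figure D4:**
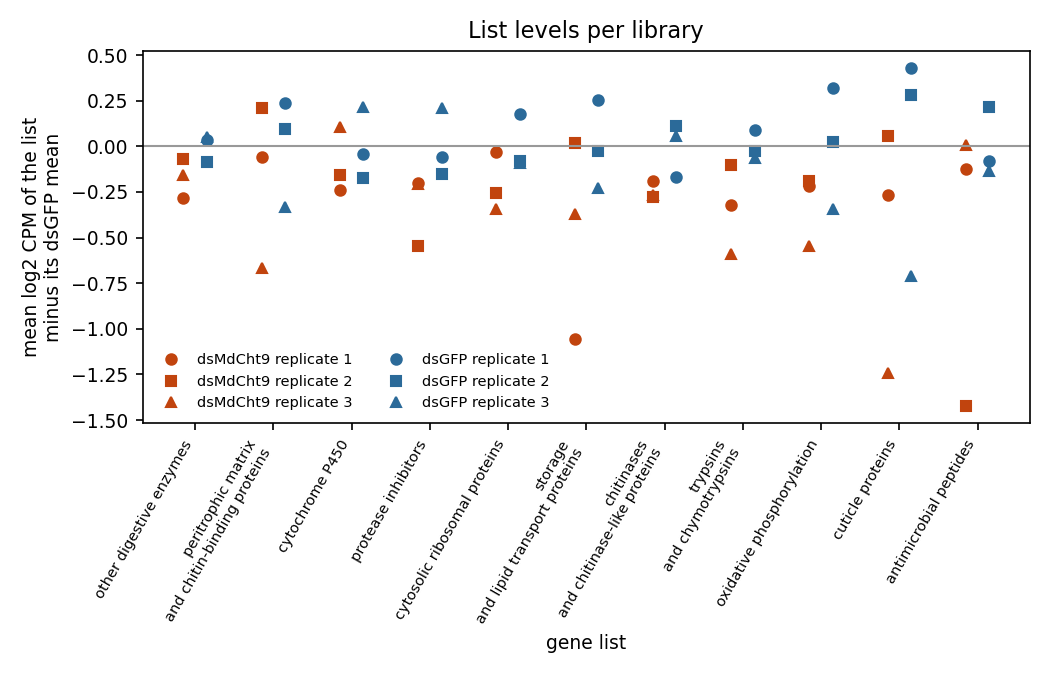
Mean log2 CPM of each of the 11 called lists in each library, relative to its mean in dsGFP (vertical axis), with dsMdCht9 in orange, dsGFP in blue and the replicate number as the marker shape. Cuticle proteins were lowest in both samples numbered 3 (-1.24 and -0.71), antimicrobial peptides in dsMdCht9 replicate 2 (-1.42) and storage proteins in dsMdCht9 replicate 1 (-1.05).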

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

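Chosen after seeing the data were the fits without both samples numbered 3, DESeq2 with the replicate block, cyclic loess offsets and the domain-based chitinase list. The count of genes passing was 0 in edgeR under each scaling, filter, threshold and left-out library and with the replicate block, and 0 in limma-voom. DESeq2 gave 13 genes (8 higher, 5 lower), and 91 with the replicate block (16 higher, 75 lower). In the simulation DESeq2 also called more unchanged genes than edgeR, and the cause of the difference here was not tested. With 3 libraries a group, changes of 2-fold were mostly not called in the simulation.

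The count of lists, 11 in the main test, was 0 with an estimated correlation, 0 with fry (directional or mixed p), 7 lower without both samples numbered 3, 7 lower and 1 higher without a filter, and 9 lower and 1 higher with cyclic loess offsets. Leaving out 1 library gave 7 to 15 lists, of which 7 to 14 were lower and 0 to 1 higher. The cuticle, trypsin, ribosomal and oxidative phosphorylation lists passed in each of these 6 fits, with medians from -0.94 to -0.29, -0.32 to -0.17, -0.31 to -0.12 and -0.48 to -0.16. The replicate block gave 12 lists and changed no call of a list except cytochrome P450, muscle and chemosensory proteins, and no call of a gene in edgeR. Chitinases defined by domain (22 genes) had a median of -0.24. The alternatives planned for the level of MdCht9 were not run, since no annotation names it.

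Sign changes were found in genes and lists that the main test did not call, and apart from the shift of all genes under library size alone (0.12) their cause was not tested. By library size alone, log2 fold changes became 0.027 (LOC101891535 and LOC101899985), 0.10 (LOC101899936), 0.010 (LOC101889717), 0.0063 (LOC101897146) and 0.0069 (LOC101893352), and list medians 0.034 (ecdysteroid), 0.013 (juvenile hormone and other detoxification), 0.0039 (lysozymes), 0.059 (haemocyte), 0.11 (DNA replication) and 0.071 (fatty acid). Without a filter the neuronal median was -0.11 and the chemosensory 0.037, and at 5 CPM the neuronal was -0.040. LOC101889717 was 0.0046 with the replicate block, 0.017 in limma-voom and 0.048 without both samples numbered 3, where LOC101891535 was 0.034, LOC101897146 0.071, and the list medians were 0.045 (immune recognition), 0.039 (DNA replication), -0.033 (RNA interference) and 0.024 (fatty acid).

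Over the 6 fits that left out 1 library, log2 fold changes ranged from -0.22 to 0.042 (LOC101891535), -0.21 to 0.066 (LOC101899985), -0.074 to 0.071 (LOC101899936), -0.62 to 0.15 (LOC101900924), -0.47 to 0.42 (LOC101889717), -0.20 to 0.026 (LOC101897146), -0.50 to 0.073 (LOC101898595), -0.37 to 0.065 (LOC101898126), -0.38 to 0.098 (LOC101893352), -0.046 to 0.28 (LOC101897720, argonaute-2) and -1.43 to 0.30 (the gene with the symbol chitinase). List medians ranged from -0.34 to 0.12 (ecdysteroid), -0.17 to 0.087 (immune recognition), -0.25 to 0.032 (tanning), -0.17 to 0.046 (haemocyte), -0.071 to 0.081 (DNA replication) and -0.15 to 0.025 (fatty acid).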

Other observations

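The tests of the replicate numbers, of larval stage, of a shared axis with the samples numbered 3, of the small scaffolds and of reads shared between gene copies, the cyclic loess offsets and the domain-based chitinase list were chosen only after the results were seen. The samples numbered 3 resembled each other across the 2 groups. In the edgeR fit with group and number, 235 genes differed between the 3 numbers. Each number was compared with the mean of the other 2, which gave 3 genes for number 1, 57 for number 2 and 545 for number 3, of which 251 were higher and 294 lower. Of the 67 cuticle proteins, 18 were lower and 6 higher in number 3 at an adjusted p under 0.05, the lower ones including LOC101888740 (larval cuticle protein 5-like), at 8.26 CPM in dsMdCht9 replicate 3 and 12.6 in dsGFP replicate 3 against 367.9 to 450.3 in the other 4 libraries (adjusted p = 0.00215). LOC101888507 (fat-body protein 1-like) lay the other way, at 448.1 and 653.8 CPM against 10.5 to 20.3. The ecdysteroid list had a median of 0.56 in number 3 against the others (camera adjusted p = 2.1e-06, and adjusted p = 0.625 with an estimated correlation), with 6 of its 20 genes higher and 0 lower at an adjusted p under 0.05.

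A glycosyl hydrolase 18 domain, the catalytic domain of chitinases, was annotated in 22 tested genes, 20 of them in the chitinase list. The list held 7 tested genes without it, LOC101893092 among them. Of the 22 with the domain, 20 were lower in dsMdCht9. Of the 2 outside the list, chosen after their values were seen, the gene with the symbol chitinase was at 172.9, 130.6 and 8.40 CPM in dsMdCht9 replicates 1, 2 and 3 and at 154.4, 395.9 and 14.1 in dsGFP replicates 1, 2 and 3. LOC101900050 (mucin-19-like) differed by -0.64 ± 0.46, or by -0.26 without dsGFP replicate 1 and -1.02 without dsMdCht9 replicate 2. Neither passed the threshold.

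The difference between the samples numbered 3 and the others may be one of larval stage, of pool or of library batch. Of the 545 genes called for number 3, 511 stayed called with all libraries thinned to the smallest total, so unequal depth does not account for the pattern, and 537 of the 544 outside the 50 most abundant genes stayed called without those 50, so a few abundant genes do not either. A difference in stage was tested through the cuticle list, which was lower in number 3 at the preset correlation (adjusted p = 1.4e-14) but not with an estimated one (adjusted p = 0.625). With an estimated correlation no list lay below that value in number 3. The test could therefore not decide, and a difference in stage stays open. Collection or library batches are not named in the labels used here and were not tested.

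The 11 lower lists may share a source other than the injected RNA. A trend of fold change with abundance was present, with a median of -0.15 for the 629 genes above 8 log2 CPM. After cyclic loess offsets that median was -0.02 and 9 of the 11 lists stayed called and lower, the ribosomal at -0.09 from -0.21, so the trend is not the whole source, while the peritrophic (median -0.18 and SD over members 0.39 before, -0.16 and 0.37 after, adjusted p = 0.0895) and storage lists (-0.23 and 0.46 before, -0.17 and 0.51 after, adjusted p = 0.215) were no longer called, which leaves the trend open for these 2. Along the axis of the samples numbered 3, the medians of 6 of the 11 lists had the same sign. At most 6 was to argue against that axis, but this limit was set after the results were seen and equals the count found. The count therefore does not decide. Of the 11, 2 lay near 0 (0.013 for storage proteins and -0.061 for other digestive enzymes). The replicate block removes a shift shared by both groups, and with it 10 of the 11 stayed called, all but cytochrome P450. Medians were then -0.32 for oxidative phosphorylation and -0.21 for ribosomal proteins. Each number is present in both groups, so a shift of equal size in both cancels in dsMdCht9 minus dsGFP with or without the block. The blocked calls therefore could not test the samples numbered 3 as a source of those 10. A shift that differed in size between the groups stays open. Since all 11 calls were lost with an estimated correlation, shared variation between libraries stays open for each of them.

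Of the 210 genes higher in dsMdCht9 at an unadjusted p under 0.05, 78 (37.1%) were on small scaffolds, those with at most 3 genes of the table, against 17.8% of all tested genes (odds ratio 2.80, Fisher's exact p = 1.7e-11), while the 171 lower genes held 16.4% (odds ratio 0.903). Genes are not independent, so this p cannot be taken at face value. The odds ratio of the real grouping was above those of the other 9 splits of the 6 samples, of which the highest was 1.90. The pattern was first seen in the real grouping, and 10 splits are too few for a share under 0.05. This rank therefore does not decide whether the pattern exceeds chance. Reads moving between copies of a gene could raise one copy at the cost of another. In 20 families with a higher small-scaffold copy, the other copies together changed in the same direction, by 0.908 of the gain of the small-scaffold copies. The ratio was 0.618 without protein takeout, the family of largest gain. Much of the remaining change was in the other copies of G-protein coupled receptor Mth2 (37.1 CPM) and heat shock protein 70 (21.1 CPM). The gain of the small-scaffold heat shock copy, LOC101891430, came mostly from dsMdCht9 replicate 3. The median ratio over families was 0.399, and 12 of the 20 showed no loss in the other copies. In 2 families the loss was larger than the gain, at ratios of -1.21 (coactosin-like protein) and -18.0 (serine/arginine repetitive matrix protein 2). The second is far beyond the size an exchange would give. An exchange of reads stays open for single families. No biological explanation was tested, and differences in sex or genotype between the pools of larvae stay open.

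The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. In edgeR the real split gave 0 genes, which all 10 of 10 splits reach by definition, so that comparison says nothing, and the highest of the others gave 21. In DESeq2 the real split gave 13 genes and the highest of the others 649, with 5 of 10 splits reaching 13. For lists the real split gave 11 and the highest other 15, with 4 of 10 reaching 11. The split with 21 and 649 genes put dsMdCht9 replicates 1 and 3 with dsGFP replicate 3, both samples numbered 3 on one side and both numbered 2 on the other, which points to a structure of the samples that follows their numbers. Of the 4 splits that part all 3 pairs, the real one gave 13 genes in DESeq2 and the others 1, 3 and 0. With the replicate block it gave 91 genes in DESeq2 and the others 4, 12 and 11, and in edgeR 888 genes at an unadjusted p under 0.05 against 307, 453 and 322. With only 4 such splits, the real one ranks first by chance in 1 of 4, and the choice of splits rests on the pairing read from the data. These counts therefore do not decide whether the real split differs from the others. By lists it did not rank first, with 12 in the blocked fit against 4, 15 and 6.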
